A study of Oryza sativa with 12 samples.

How the data were processed

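Messenger RNA of rice seedlings was measured on 12 one-colour (Cy3) Agilent arrays, 3 for each of 4 groups: wild-type shoot, wild-type root, oshho3 knockout shoot and oshho3 knockout root. Per the labels, the seedlings were 27 days old and supplied with sufficient nitrogen, and total RNA was turned into labelled cRNA by linear amplification. The groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

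Per the file headers, each array was scanned and read out with Agilent Feature Extraction 9.1.3.1, and the submitters' processing notes name version 9.1. The scanner files give linear spot intensity: the processed signal is, per the file headers, the spot intensity after the software's spatial detrending and background handling, with surrogate values for dim spots and no scaling between arrays. Raw pixel means, pixel medians and local background medians are given beside it. The authors' deposited table of the series holds linear intensity as well. Its values were set against the scanner files and equalled the raw pixel median for 100% of the spots on all 12 arrays, with column medians from 79 to 170, so it is neither background-subtracted nor scaled, and it was used only as an alternative. Another 69 lines of it were blank. The genome build behind the array design is not given in the sources used here.

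A pixel median cannot lie more than 1 SD from the pixel mean of the same spot. Of 541812 spot values, 24 on 4 root arrays broke this limit (with a tolerance of 1.05 SD), and the largest gap among all other spots was 0.797 SD. Of the 24, 12 belonged to the same 4 spots of 3 ammonium transporter loci on the 3 knockout root arrays, and 5 to spots of nitrate transporters. The authors' table carries these medians. The processed signal used for the values reported here derives from pixel means, and for Os04g0509600 and Os05g0468700, with 9 of the 24 values, it could be set beside that of another spot of the same probe. For the other values, whether further columns were affected was not established. For this reason the pixel mean was added as an alternative beside the authors' pixel median.

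Each array has 45151 spots. The 2007 control spots were left out, which left 43144 gene spots with 37896 distinct probe sequences. Of these probes, 37427 had 1 locus name, 132 had several and 337 had none, and 28324 loci had a probe. On 1354 spots the probe name and the gene name gave different loci. None of the 28324 loci was found in the reference gene table used here (39387 genes, assembly ASM3414082v1), so loci are named as in the scanner files, product names are those of the files, which can be old, and no coordinates are given. Spots of 1 probe were averaged. A gene was represented by its probe of highest mean signal over the 12 arrays. Genes with an outlier spot on an array of the fit were left out of that comparison (99 in shoot, 97 in root, 93 in the difference between tissues and 103 between wild-type tissues).

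The processed signal was log2-transformed and each array's 75th percentile was subtracted. That percentile ran from 669 to 797 on the 6 shoot arrays, was 161, 289 and 153 on wild-type root arrays 1 to 3, and 307, 268 and 468 on knockout root arrays 1 to 3. Well above background were 67.4% of the spots on wild-type root array 1, 68.0% on wild-type root array 3, and 74.3% to 78.3% on the others. On knockout root array 1, 2 spots were saturated, and none elsewhere. Correlations between replicates of a group ran from 0.980 to 0.991 across spots. With 3 arrays per group, their number limits the precision.

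Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 arrays with 4 group means, which left 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels state no test. A gene entered a comparison if its probe was well above background on all 3 arrays of at least 1 group compared. The comparison of wild-type root with shoot also required an absolute log2 change of 1. Where no probe of a gene was well above background on any of the 3 arrays of 1 group, only a bound is given, as "at least" so many fold: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background, all on the normalised log2 scale. Errors of log2 changes are standard errors of the fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

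The 12 arrays lay on 3 slides, each scanned once and holding 1 array of every group, and the replicate number equalled the slide. The slide was therefore used as a block and values within each slide were computed. A group always had the same position on its slide, so position and group cannot be told apart.

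There were 29 gene lists, defined by locus numbers or by words in the product name. Lists with at least 3 measured members were tested with limma's camera (preset correlation of 0.01, and an estimated correlation as an alternative) and fry, with Benjamini-Hochberg adjustment over the lists. Genes are named by this rule: in each genotype comparison, the 10 largest rises and 10 largest falls past the threshold with all knockout values on one side of the wild-type values, 1 locus name and an informative product name, every NIGT1/HHO family member, every member past the threshold of the ammonium transporter, nitrate transporter and nitrogen assimilation lists with up to 2 others of highest signal, and up to 4 members past the threshold from every other list. For the difference between tissues, the 10 genes of smallest adjusted p with a product name were taken, together with the family and nitrogen lists. For wild-type root against shoot, the family, nitrogen and tissue marker lists were taken. Samples, tests, lists, this rule and the alternatives were chosen before the data were examined, except those named here and in the closing section. What counts as an informative product name was narrowed after a first table of named genes had been seen, which removed some of the largest changes (among them Os07g0511100 and Os06g0265100) from the named genes. The products that contradicted a list were dropped from it after the product names had been read.

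The fitting steps were tested on simulated data made from the means and spreads of these arrays. At a 2-fold change the shoot step, over 20912 genes, recovered 57% of 100 changed genes, and at 4-fold 94% of 100, with 8 false calls. The root step, over 20539 genes, recovered 73% and 90% of 100 each, with 12 false calls. The step for the difference between tissues, over 18346 genes, recovered 57.5% of 179 genes at 2-fold and 86.5% of 178 at 4-fold, with 10 false calls. No call had the wrong direction. The simulated noise was normal, independent between genes and, for a gene, of equal spread on all 12 arrays. It held no array-wide errors, so these counts need not hold for the real arrays.

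Alternatives were normexp background correction (offset 50) of pixel means, quantile and median scaling, no filter or a filter on all 12 arrays, every probe alone or the mean of a gene's probes, only the arrays of the groups compared, the replicate number or slide as a block, eBayes with trend and robust, a minimum fold, the authors' deposited table, array weights, and leaving out each array in turn. Chosen after seeing the data were quantile and cyclic loess scaling within each tissue, the pixel mean, and leaving out wild-type root arrays 1 and 3.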

Results

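OsHHO3 is a rice transcription factor of the NIGT1/HHO branch of the GARP family, whose members are known as nitrate-inducible repressors of nitrogen and phosphate uptake genes. Transcripts of 27-day-old seedlings grown with sufficient nitrogen were compared between wild type and an oshho3 knockout in shoot and in root, with 3 arrays in each of the 4 groups. Signal over background was lowest on wild-type root arrays 1 and 3, where 67.4% and 68.0% of the spots were well above background. All levels are log2 signals relative to the array's 75th percentile, changes are log2 differences ± SE with n = 3 arrays per group, and p-values are limma's, adjusted by Benjamini-Hochberg.

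The question of the genotype comparisons was which transcripts depend on OsHHO3. The files used do not say which locus was knocked out, so all 4 measured NIGT1/HHO family loci are given, and a probe outside the altered part of a gene would not check the knockout. All 4 family members were higher in the knockout in both tissues. Os02g0325600 rose from -4.64 ± 0.22 to -1.52 ± 0.29 (mean ± SD, n = 3) in shoot and from -1.36 ± 0.13 to -0.025 ± 0.066 in root, changes of 3.12 ± 0.16 (adjusted p = 5.74e-06) and 1.33 ± 0.16 (adjusted p = 0.00213). Os03g0764600 rose from 3.32 ± 0.13 to 4.87 ± 0.57 in shoot and from 2.49 ± 0.16 to 3.87 ± 0.44 in root, by 1.55 ± 0.28 (adjusted p = 0.0238) and 1.38 ± 0.28 (adjusted p = 0.0258). Os07g0119300 rose by 1.57 ± 0.19 in root (adjusted p = 0.00226) and by 0.91 ± 0.19 in shoot (adjusted p = 0.0482, and 0.103 with the slide as a block). Os12g0586300 rose by 1.14 ± 0.20 in shoot (adjusted p = 0.0218, and 0.05003 with the block) and by 0.84 ± 0.20 in root (adjusted p = 0.0476, and 0.0746 with the block). As a list, 4 of 4 members rose in each tissue, also when adjusted over the list alone, with a median of 1.34 in shoot (adjusted p = 5.04e-10, blocked 3.37e-10) and 1.36 in root (adjusted p = 5.98e-06, blocked 3.37e-06). The adjusted p = 0.106 in shoot and 0.132 in root with an estimated correlation. Within slides 1, 2 and 3 the list's median was 1.74, 1.59 and 0.72 in shoot and 1.38, 1.35 and 1.23 in root. The shoot call of Os07g0119300 was lost in 23 of 30 alternative settings and the root call of Os12g0586300 in 21 of 30.

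**Figure D1:**
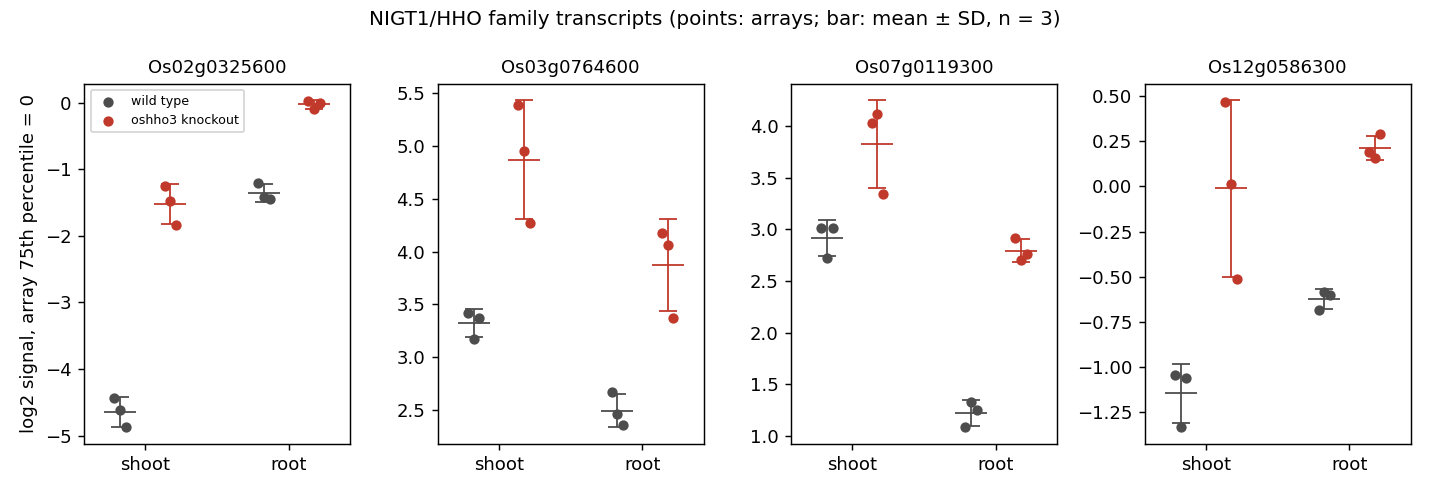
Log2 signal, with the array's 75th percentile at 0, of the 4 NIGT1/HHO family loci in shoot and root of wild type (grey) and knockout (red). Points are arrays, bars the mean ± SD (n = 3), and the y axis differs between the 4 panels; Os02g0325600 shows the widest gap, from -4.64 to -1.52 in shoot.

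In knockout shoots, Os12g0503000, an allantoin permease (a carrier of purine-derived nitrogen), rose by 3.24 ± 0.26 (adjusted p = 0.000123), and Os10g0580400, similar to a urea active transporter, by 2.94 ± 0.41 (adjusted p = 0.00672). Os03g0794500, a glutamate dehydrogenase, rose by 0.73 ± 0.09 (adjusted p = 0.00378). Os04g0355900, similar to a flavonol glucoside malonyltransferase, was at least 148-fold higher (adjusted p = 5.61e-06) and Os10g0419400, similar to SIPL, rose by 5.79 ± 0.18 (adjusted p = 2.86e-07), from -5.68 ± 0.21 to 0.11 ± 0.15 (mean ± SD, n = 3).

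Of 20912 genes tested in shoot, 237 rose and 47 fell, and 144 and 18 of these by 2-fold or more. With the slide as a block 186 rose and 32 fell, and 203 of the 284 genes were called in both fits. The median of the risen genes was 1.27, 1.08 and 1.19 within slides 1, 2 and 3, and that of the fallen genes -0.95, -0.81 and -0.82. For 41 of the 284 only a bound on the fold could be given.

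The other large rises in shoot were Os05g0124700, a deoxynucleoside kinase (at least 8.55-fold, adjusted p = 1.01e-06), Os05g0417400, a universal stress protein (at least 3.13-fold, adjusted p = 0.0147), Os04g0249600, similar to the senescence-associated protein DIN1 (3.31 ± 0.19, adjusted p = 1.37e-05). Os10g0178500, a UDP-glucosyltransferase, rose by 3.15 ± 0.34 (adjusted p = 0.0012). Os04g0394100, a glycerophosphoryl diester phosphodiesterase, rose by 3.28 ± 0.31 (adjusted p = 0.000475) and was well above background on 1 of 3 wild-type arrays. Among the named falls, Os11g0461000, an anthocyanidin glucosyltransferase, fell at least 8.69-fold (adjusted p = 0.000401). Os07g0607400, a pectin lyase fold protein, fell by 3.76 ± 0.63 (adjusted p = 0.0167, and 0.0531 with the block) and was well above background on 2 of 3 knockout arrays. Os02g0677300, similar to the cold-response regulator CRT/DRE binding factor, fell at least 2.17-fold (adjusted p = 0.0104). Os10g0566400, a RING-H2 finger protein, fell by 1.502 ± 0.16 (adjusted p = 0.000939), and Os03g0287400, a LOB domain protein, by 1.66 ± 0.32 (adjusted p = 0.0385, and 0.054 with the block). The remaining named falls lay between -1.32 for Os10g0508700, a pectinesterase inhibitor, and -1.04 for Os07g0670300, a C2 domain protein, and comprised also Os10g0540200 (selenium-binding protein-like), Os06g0703900 (homeodomain-like) and Os05g0107900, similar to a dehydration-induced protein (adjusted p = 0.03, and 0.0583 with the block).

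The nitrogen lists moved little gene by gene in shoot. None of 8 ammonium transporters passed the threshold (1 did when adjusted over the list alone), but the list lay higher as a whole, with a median of 0.43 (adjusted p = 0.00315, blocked 0.00139; adjusted p = 0.237 with an estimated correlation) and 0.39, 0.31 and 0.67 within the slides. Its brightest members were Os05g0468700 at 0.16 (adjusted p = 0.758) and Os04g0509600 at 0.68 (adjusted p = 0.0658). Neither any of 9 nitrate transporters (median -0.04, adjusted p = 0.883; Os06g0581000 at 0.10 and Os08g0155400 at -0.05) nor any of 9 NRT1/PTR transporters (median -0.11, adjusted p = 0.521) passed. Of 14 nitrogen assimilation enzymes 1 rose, the glutamate dehydrogenase above, and 1 fell, Os08g0468700, whose product is given as unknown and which is in the list by its locus (fell by 0.92 ± 0.12, adjusted p = 0.00394). Adjusted over the list alone 2 rose and 3 fell, and the list did not shift (median -0.05, adjusted p = 0.883). Its brightest other members were nitrite reductase Os01g0357100 at -0.77 (adjusted p = 0.1) and glutamine synthetase Os02g0735200 at 0.42 (adjusted p = 0.197).

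Of 25 lists tested in shoot, 6 shifted up and 1 down with camera's preset correlation and none with an estimated one (3 at an unadjusted p under 0.05), while by fry 2 lists moved one way and 8 changed in either direction. Besides the family and the ammonium transporters, 49 WRKY factors (defence and stress regulators) lay higher by a median of 0.18 (adjusted p = 0.00183; adjusted p = 0.300 with an estimated correlation) with no single member past the threshold, also over the list alone. Of 6 fermentation and hypoxia genes (median 0.41, adjusted p = 0.00521; adjusted p = 0.237 with an estimated correlation) 1 rose, L-lactate dehydrogenase Os02g0105400 by 0.78 ± 0.16 (adjusted p = 0.0437), and 2 over the list alone. The 11 dehydrins and LEA proteins (median 0.21, adjusted p = 0.0472; adjusted p = 0.5 with an estimated correlation) and the 36 histone and DNA replication genes (median 0.09, adjusted p = 0.0262; adjusted p = 0.704 with an estimated correlation) shifted with no member past the threshold. The 17 expansins and xyloglucan endotransglucosylases, which loosen cell walls, lay lower by a median of -0.44 (adjusted p = 0.00243; adjusted p = 0.300 with an estimated correlation), with no member past the threshold. Within slides 1, 2 and 3 the medians were 0.16, 0.08 and 0.28 for WRKY factors and 0.50, 0.31 and 0.49 for fermentation. They were 0.13, 0.02 and 0.28 for LEA proteins, 0.02, 0.18 and 0.04 for histones and -0.76, -0.22 and -0.27 for expansins. All 7 shifts kept their call with the slide as a block.

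Among the other 18 lists in shoot, members passed in nitrogen assimilation, given above, and in 3 more. Of 17 phosphate starvation genes (median -0.03, mean 0.25, adjusted p = 0.151) 2 rose, and 6 rose and 1 fell over the list alone. Os06g0603600, an SPX domain gene of phosphate homeostasis, rose by 0.69 ± 0.12 (adjusted p = 0.0235, and 0.0686 with the block) and Os03g0827500 by 0.81 ± 0.15 (adjusted p = 0.0268, and 0.0698 with the block). Of 43 photosynthesis genes (median -0.07, adjusted p = 0.883) 1 rose, PsbQ family gene Os02g0631100, by 1.32 ± 0.22 (adjusted p = 0.0167). Of 44 pathogenesis-related proteins and chitinases (median 0.12, adjusted p = 0.442) 2 rose, chitinase Os01g0687400 by 1.14 ± 0.18 (adjusted p = 0.0118) and a PR-1 gene, Os07g0125000, by 0.59 ± 0.12 (adjusted p = 0.0428). No member passed among sulfate uptake (12 genes, adjusted p = 0.809), potassium transport (26, 0.553), iron deficiency (8, median 0.06, 0.883), aquaporins (8, 0.883), chlorophyll synthesis (10, 0.442) or cytokinin (4, 0.883), where the last value in parentheses is the list's adjusted p. The same held for jasmonate (31, 0.372), diterpenoid phytoalexins (6, 0.883), class III peroxidases (35, 0.883), heat shock proteins (115, 0.883), the circadian clock (7, 0.248) and cytosolic ribosomal proteins (133, 0.0842). The early nodulin 93 and abscisic acid lists had 1 member tested each (0.34 and -0.03, adjusted p = 0.863 and 0.993), none of the 4 root marker loci was measured in shoot, and the CEP and CLE peptide list had no locus on the array. The median, mean and test differed in sign for phosphate starvation, photosynthesis, aquaporins, diterpenoid phytoalexins, peroxidases and heat shock proteins, none of which shifted against other genes by camera. By fry the phosphate starvation list moved upward (adjusted p = 0.0307).

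The shoot count differed between settings: 30 genes were called with normexp correction of pixel means, 175 from the authors' deposited table, 185 from pixel means, 148 with only the shoot arrays in the fit and 575 with array weights. Without wild-type shoot array 1, 2 or 3 it was 154, 152 and 163.

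In knockout roots, 4 of 9 ammonium transporters rose (5 over the list alone), with a list adjusted p = 0.0521 with an estimated correlation: Os02g0620500 by 2.71 ± 0.23 (adjusted p = 0.000335), Os04g0509600 by 1.76 ± 0.15 (adjusted p = 0.000335), Os01g0831300 by 1.64 ± 0.27 (adjusted p = 0.0109), and Os05g0468700 by 1.17 ± 0.12 (adjusted p = 0.00126). Of 15 nitrogen assimilation enzymes 2 rose (list adjusted p = 0.113 with an estimated correlation). Glutamine synthetase Os03g0223400, the root isozyme, rose by 1.498 ± 0.26 (adjusted p = 0.014), and Os05g0555600, similar to NADH-glutamate synthase, was at least 5.08-fold higher (adjusted p = 0.00533). In the iron list 7 of 12 members rose, with a median of 1.44 (list adjusted p = 0.105 with an estimated correlation). Rubisco small subunit gene Os12g0274700 fell by 4.71 ± 0.64 (adjusted p = 0.00462), and its change was -3.82 (adjusted p = 0.00161) without wild-type root array 1, on which photosynthesis transcripts stood apart.

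Of 20539 genes tested in root, 668 rose and 129 fell, and 261 and 55 of these by 2-fold or more. With the slide as a block 510 rose and 92 fell, and 542 of the 797 were called in both fits. The median of the risen genes was 0.97, 0.78 and 0.77 within slides 1, 2 and 3, and that of the fallen genes -0.94, -0.61 and -1.06. For 90 of the 797 only a bound on the fold could be given.

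The ammonium transporter list rose by a median of 0.62 (adjusted p = 1.24e-05, blocked 1.03e-05; adjusted p = 0.0521 with an estimated correlation), and by 0.65, 0.64 and 0.64 within the slides. Its brightest members not past the threshold were Os02g0620600 at 0.62 (adjusted p = 0.057, and 0.00978 with the block) and Os01g0870300 at 0.15 (adjusted p = 0.909), which was -0.19 in the authors' deposited table and -0.21 from pixel means. Spots of Os02g0620500, Os04g0509600 and Os05g0468700 on all 3 knockout root arrays held deposited pixel medians that exceeded their pixel means 1.44- to 2.60-fold, beyond what the spots' pixel SDs allow. The probe of Os05g0468700 had another spot with ordinary medians, whose processed signals were 694, 541 and 755 on knockout root arrays 1 to 3, against 653, 539 and 769 on the spot concerned. Such a spot of Os04g0509600 read 1720, 1540 and 2260, against 1670, 1520 and 2100 and 1590, 1440 and 2230 on the 2 spots concerned. For Os02g0620500, with a single spot, whether the processed signal was affected was not established. The 3 loci were 2.08, 2.19 and 1.63 higher in the authors' deposited table (adjusted p = 3.54e-05, 1.3e-05 and 1.3e-05). They were 1.21, 1.69 and 1.01 from pixel means (0.00214, 4.88e-05 and 0.000331) and 1.24, 1.21 and 0.72 with normexp (0.0199, 0.419 and 0.436). Over all alternatives the adjusted p ran from 3.54e-05 to 0.0199, from 1.3e-05 to 0.419 and from 1.3e-05 to 0.436. The lowest of each was that of the deposited table, which carries the raised medians. Os01g0831300 was 0.30 higher in the deposited table and 0.26 from pixel means, and lost its call in both.

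Of 8 nitrate transporters 2 rose (4 over the list alone): Os01g0704100, similar to a high-affinity nitrate transporter, by 1.01 ± 0.21 (adjusted p = 0.0313), and Os02g0112600 by 0.88 ± 0.16 (adjusted p = 0.0169). Their calls were lost in 8 of 30 and 8 of 29 alternative settings, and their changes ran down to 0.66 and 0.0037. Deposited medians of Os01g0704100 and Os03g0235900 were also among those beyond the limit of their pixel SDs. The list as a whole did not shift (median 0.35, adjusted p = 0.185), with Os06g0581000 at 0.35 (adjusted p = 0.165) and Os08g0155400 at -0.27 (adjusted p = 0.507). Of 15 nitrogen assimilation enzymes 2 rose, the glutamine and glutamate synthesis genes above, and 6 over the list alone. The list lay higher by a median of 0.28 (adjusted p = 0.000794, blocked 0.000605; adjusted p = 0.113 with an estimated correlation) and by 0.14, 0.21 and 0.26 within the slides, and lost the call with normexp. Nitrite reductase Os01g0357100 was at 0.70 (adjusted p = 0.0705) and glutamine synthetase Os02g0735200 at 0.11 (adjusted p = 0.683).

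In the iron list 7 of 12 members rose (10 over the list alone), and the median of 1.44 (adjusted p = 1.95e-08, blocked 1.09e-08; adjusted p = 0.105 with an estimated correlation) was 1.56, 1.12 and 1.42 within the slides. Its members make and move nicotianamine and the mugineic acids with which grasses take up iron, or regulate these genes. Os02g0650300, an oligopeptide transporter, rose by 2.78 ± 0.36 (adjusted p = 0.0038), Os11g0134900, a major facilitator antiporter, by 2.27 ± 0.24 (adjusted p = 0.00126), Os03g0237100, a reductase, by 1.46 ± 0.16 (adjusted p = 0.00181) and Os03g0379300, a helix-loop-helix factor, by 1.43 ± 0.14 (adjusted p = 0.000911). Outside the list, Os08g0466600, similar to a metal-nicotianamine transporter, was at least 32.1-fold higher (adjusted p = 0.000209).

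**Figure D2:**
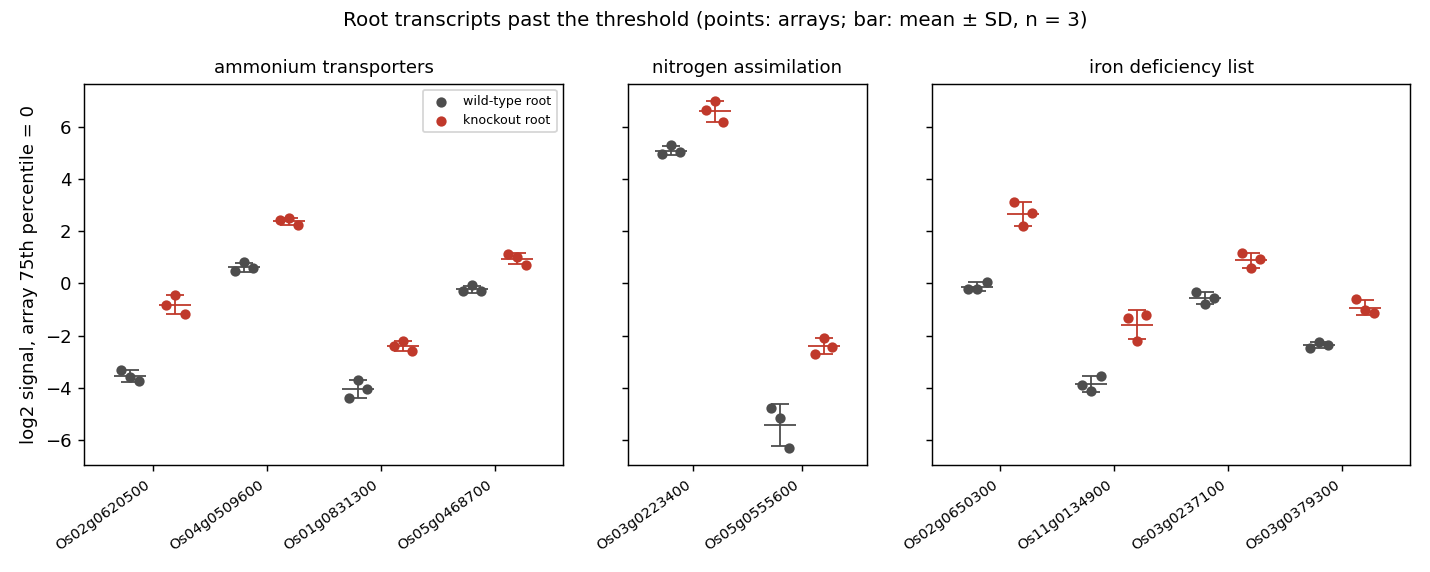
Log2 signal, with the array's 75th percentile at 0, of root transcripts from the ammonium transporter, nitrogen assimilation and iron lists in wild type (grey) and knockout (red). Points are arrays and bars the mean ± SD (n = 3); the wild-type points of Os05g0555600 were not well above background, and Os02g0620500 rose by 2.71 and Os02g0650300 by 2.78.

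Other large rises in root were those of S-adenosylmethionine synthetase Os01g0293000 (4.22 ± 0.32, adjusted p = 0.00018), which makes the methyl donor from which nicotianamine and ethylene derive, and of Os11g0170900, a BURP domain protein (at least 8.77-fold, adjusted p = 0.000244). The malonyltransferase-like Os04g0355900 was at least 6.44-fold higher (adjusted p = 0.000883). Cytochromes P450 Os02g0569400 and Os06g0641500 were at least 4.06-fold and 3.17-fold higher (adjusted p = 0.0184 and 0.00106). The lipid-transfer protein Os11g0620300 was at least 1.54-fold higher (adjusted p = 0.00126), but lay at -0.12 in the authors' deposited table and at -0.11 from pixel means.

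Among the largest falls in root, chitinase Os10g0416500 fell by 3.40 ± 0.46 (adjusted p = 0.00462), chitin-binding Os11g0592200 by 3.64 ± 0.66 (adjusted p = 0.0183) and germin-like Os04g0617900 by 2.75 ± 0.44 (adjusted p = 0.0104). Os09g0472900, similar to a blight-associated protein, fell by 4.70 ± 1.00 (adjusted p = 0.0322) and thaumatin-like Os12g0628600 by 3.26 ± 0.61 (adjusted p = 0.0202), each well above background on 1 of 3 knockout arrays. Of 48 pathogenesis-related proteins and chitinases 4 fell and 1 rose, also over the list alone. Os10g0416500, Os12g0628600 and the amylase and trypsin inhibitor Os03g0661600 (fell by 1.69 ± 0.27, adjusted p = 0.0103) were lower, and chitinase Os10g0416100 was higher (0.58 ± 0.13, adjusted p = 0.0428, and 0.0814 with the block). That list lay lower by a median of -0.10 (adjusted p = 0.00905, blocked 0.00838; adjusted p = 0.450 with an estimated correlation), at 0.11, -0.15 and -0.16 within the slides, and lost the call in the authors' deposited table and with normexp.

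Other large falls in root were those of ribonuclease T2 gene Os09g0537700, at least 21.2-fold (adjusted p = 0.0039), and the plasma membrane aquaporin Os09g0541000, which fell by 4.37 ± 0.80 (adjusted p = 0.0184; well above background on 2 of 3 knockout arrays). Type 3 metallothionein Os01g0200700 fell by 3.52 ± 0.58 (adjusted p = 0.0115) and Rubisco activase-like Os11g0707000 by 3.04 ± 0.72 (adjusted p = 0.0459). Without wild-type root array 1 the fitted changes of these 4 were -4.45, -3.33, -2.67 and -2.02 (adjusted p = 0.00156, 0.0191, 0.0023 and 0.0362). Of 37 photosynthesis genes measured in root, which serve in the list as markers of green tissue, only Os04g0473150, similar to photosystem II protein D1, fell by itself (by 2.41 ± 0.57, adjusted p = 0.0459, and 0.0573 with the block), and none did over the list alone. Rubisco gene Os12g0274700 is not a member of this list. The list as a whole lay lower by a median of -1.18 (adjusted p = 2.12e-10, blocked 8.70e-12; adjusted p = 0.450 with an estimated correlation). Within the slides the list's median was -2.08, -0.27 and -1.13, and without wild-type root array 1 it was -0.508. The median level of the 37 genes was 0.98, -0.54 and -0.90 on wild-type root arrays 1 to 3 and -0.88, -1.10 and -1.95 on knockout root arrays 1 to 3, so that wild-type root array 1 stood apart. Without wild-type root array 1, 46 of the 129 falls and 291 of the 668 rises were still called.

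**Figure D3:**
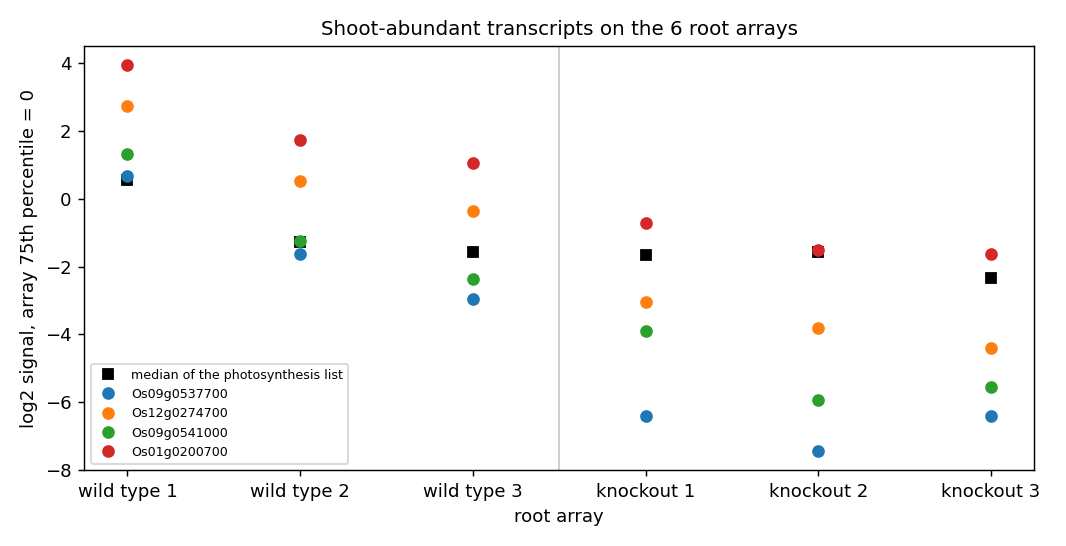
Log2 signal, with the array's 75th percentile at 0, on the 6 root arrays (x axis, by group and replicate number) of 4 shoot-abundant transcripts (circles) and the median of all 43 loci of the photosynthesis list (squares). The list's median is 0.55 on wild-type array 1 and between -1.28 and -2.33 on the other arrays; the knockout points of Os09g0537700, and 1 of 3 of Os09g0541000, were not well above background.

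Of 26 lists tested in root, 4 shifted up and 4 down with camera's preset correlation and none with an estimated one (4 at an unadjusted p under 0.05), while by fry 8 lists moved one way and 14 changed in either direction. The 133 cytosolic ribosomal proteins lay lower by a median of -0.10 (adjusted p = 1.80e-06; adjusted p = 0.561 with an estimated correlation), at -0.24, -0.08 and 0.01 within the slides, with no member past the threshold. In the authors' deposited table the cytosolic ribosomal proteins lay at 0.02 and the call turned upward (adjusted p = 0.000658). The 41 histone and DNA replication genes lay lower by a median of -0.15 (adjusted p = 0.000156; adjusted p = 0.288 with an estimated correlation), at -0.20, -0.21 and -0.07 within the slides, and lost the call in the deposited table. Their 1 member past the threshold, with none over the list alone, was histone H2A gene Os05g0113900 (fell by 0.44 ± 0.11, adjusted p = 0.0479, and 0.0797 with the block). All 8 shifts kept their call with the slide as a block.

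Among the other 18 lists in root, none shifted against other genes by camera. By fry the sulfate, NRT1/PTR and potassium lists moved upward (adjusted p = 0.0324, 0.0224 and 0.0422). In the first, 4 of 14 sulfate uptake and assimilation genes rose (5 up and 1 down over the list alone; list adjusted p = 0.189). Sulfate transporters rose, Os03g0195800 by 1.92 ± 0.33 (adjusted p = 0.0137; well above background on 2 of 3 wild-type arrays) and Os03g0196000 by 1.27 ± 0.25 (adjusted p = 0.0232). So did ATP sulfurylase Os03g0743900 by 0.61 ± 0.13 (adjusted p = 0.0309, and 0.0592 with the block) and serine acetyltransferase Os05g0533500 by 0.51 ± 0.12 (adjusted p = 0.0437). Of 17 phosphate starvation genes 2 rose and 1 fell, also over the list alone (list adjusted p = 0.996). Purple acid phosphatases rose, Os11g0151700 by 2.37 ± 0.36 (adjusted p = 0.00783; well above background on 1 of 3 wild-type arrays) and Os12g0637100 by 0.85 ± 0.11 (adjusted p = 0.00294). The calls of these 2 were lost in 5 of 29 and 3 of 30 alternative settings, and the change of Os11g0151700 ran down to 0.011. The SPX gene Os06g0603600 fell by 0.54 ± 0.12 (adjusted p = 0.0394, and 0.0788 with the block). Peroxidases Os03g0762300 and Os09g0471100 rose by 1.38 ± 0.22 (adjusted p = 0.01) and 0.67 ± 0.11 (adjusted p = 0.0121) among 62 (list adjusted p = 0.615), and WRKY factor Os03g0758000 by 0.71 ± 0.14 (adjusted p = 0.0233) among 48 (0.257). Potassium channel Os01g0648000 rose by 0.49 ± 0.11 (adjusted p = 0.0409) among 22 (0.136; 3 over the list alone). Allene oxide synthase Os02g0218800 of jasmonate synthesis rose by 0.37 ± 0.08 (adjusted p = 0.0379, and 0.0698 with the block) among 27 (0.615). Among 106 heat shock genes (0.413) Os06g0163000 fell by 0.80 ± 0.10 (adjusted p = 0.00334) and the heat shock factor Os07g0178600 rose by 0.57 ± 0.12 (adjusted p = 0.0335; 2 of 3 wild-type arrays), though it lay at -0.34 in the deposited table. Among 8 NRT1/PTR transporters (0.0721; 2 over the list alone) Os04g0691400 rose by 1.09 ± 0.25 (adjusted p = 0.0388; 1 of 3 wild-type arrays) and lay at -0.13 in the deposited table. Aquaporins (8 genes, median 0.13, mean -0.51, 0.773) had 1 member past the threshold, Os09g0541000. No member passed among chlorophyll synthesis (8, 0.136), root markers (3, 0.711), cytokinin (4, 0.788), diterpenoid phytoalexins (4, 0.225), fermentation (8, 0.136), LEA proteins (12, 0.711), the clock (7, 0.421) and expansins (37, 0.204). The single members tested of the early nodulin 93 and abscisic acid lists lay at 1.01 and -0.12 (adjusted p = 0.152 and 0.777). The median, mean and test differed in sign for phosphate starvation, aquaporins, peroxidases and heat shock proteins.

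The root count was 11 with normexp, and the share of rises among the calls, 83.8%, was 49.5% in the authors' deposited table (354 up and 361 down) and 45.8% from pixel means (380 up and 450 down). It was 286 genes with only the root arrays in the fit and 246, 118 up and 128 down, without both dim wild-type arrays, 1 and 3. With array weights it was 2086. Without wild-type root array 1, wild-type root array 3 or knockout root array 1 it was 380, 311 and 228.

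Genes that rose in the knockout rose in both tissues more often than independent lists would. Among 18346 genes tested in both, 208 rose in shoot and 562 in root, and 57 rose in both, against 6.37 for independent lists of these sizes (Fisher's exact test, two-sided p = 3.18e-38; 41 with the block). They included the 4 family members, malonyltransferase-like Os04g0355900, S-adenosylmethionine synthetase Os01g0293000 and the urea transporter-like Os10g0580400. Only 2 genes fell in both (0.218 for independent lists, Fisher's exact p = 0.0201; 1 with the block). They were Os05g0304900, a glycoside hydrolase, and the non-coding transcript Os08g0100300. Opposite changes were found for 3 genes that rose in shoot and fell in root (1.13 for independent lists, Fisher's exact p = 0.105), Os06g0603600, Os04g0516600 and Os08g0233600. The opposite held for 1 that fell in shoot and rose in root (1.23 for independent lists, Fisher's exact p = 1), the DnaJ chaperone Os08g0452900. These last genes are named because their counts are small and were chosen after their values were seen. The tissues had separate control arrays, but the spread of each gene was estimated from the arrays of both tissues together. A gene with a small estimated spread is thus more readily called in both tissues, which Fisher's test does not allow for. The Fisher p-values therefore do not measure the overlap of independent tests. With only the arrays compared in each fit, the spread is not shared, and 25 genes rose and 0 fell in both. No count for independent lists is given for those fits. The count of 59 in both tissues was 124 with array weights, 5 with normexp, 24 from the authors' deposited table, 25 from pixel means, 25 with only the arrays compared, 34 with a minimum of 2-fold and 18 without both dim wild-type root arrays. It was 35, 32, 36, 37, 29 and 37 without wild-type shoot array 1 or 2, wild-type root array 1 or 3, or knockout root array 1 or 2.

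No list was tested for a difference of the knockout effect between root and shoot. Of the ammonium transporters, Os02g0620500 rose more in root by 2.61 ± 0.32 (adjusted p = 0.00563, and 0.0162 with the block), Os04g0509600 by 1.09 ± 0.21 (adjusted p = 0.0493, and 0.111 with the block) and Os05g0468700 by 1.01 ± 0.17 (adjusted p = 0.0321, and 0.0724 with the block). The helix-loop-helix gene Os03g0379300 of the iron list rose more in root by 1.76 ± 0.20 (adjusted p = 0.00402). Family member Os02g0325600 rose less in root than in shoot, by -1.79 (adjusted p = 0.00564, and 0.00444 with the block), while the differences of Os07g0119300 (0.66, adjusted p = 0.305), Os12g0586300 (-0.30, adjusted p = 0.685) and Os03g0764600 (-0.18, adjusted p = 0.883) did not pass.

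Of 18346 genes tested for this difference, 73 lay higher and 55 lower in root than in shoot, and with the block 55 and 45, of which 84 were called in both fits. Within slides 1, 2 and 3 the median was 1.25, 1.10 and 1.15 for the higher and -1.83, -1.68 and -1.60 for the lower genes. The smallest adjusted p-values belonged mostly to genes that rose more in shoot than in root: Os10g0419400 (-4.70 ± 0.25, adjusted p = 3.38e-05), methylene-tetrahydrofolate dehydrogenase Os09g0327300 (-1.997 ± 0.14, adjusted p = 0.000307), DIN1-like Os04g0249600 (-3.21 ± 0.26, adjusted p = 0.000561). They were followed by Os05g0124700 (-2.99 ± 0.28), cytochrome P450 Os02g0221900 (-2.69), phosphate transporter Os04g0186400 (-2.22 ± 0.21) and protein kinase Os10g0405100 (-1.10 ± 0.10), all 4 with an adjusted p = 0.00105. Tyrosine phosphatase Os09g0135700 lay at -1.16 ± 0.12 (adjusted p = 0.00244). Cytochrome P450 Os06g0641500 rose more in root (3.77 ± 0.43, adjusted p = 0.00402). The wild-type signals of Os05g0124700 and Os06g0641500 were not well above background where they rose, so their differences are fitted values. Of the nitrogen assimilation genes, nitrite reductase Os01g0357100 (1.47, adjusted p = 0.0371, and 0.05 with the block), Os08g0468700 (1.22 ± 0.17, adjusted p = 0.00988) and glutamate dehydrogenase Os03g0794500 (-0.69 ± 0.13, adjusted p = 0.0483, and 0.0869 with the block) differed. The count was 2 with normexp, 489 with array weights and 82 without both dim wild-type root arrays. It was 59, 73, 70, 70, 52, 70 and 208 without wild-type shoot array 1, 2 or 3, wild-type root array 3, or knockout root array 1, 2 or 3.

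Wild-type root and shoot differed widely. The root-specific protein gene Os02g0662000 was at least 7303-fold higher in root (adjusted p = 5.58e-11), and Os10g0551800 at least 631-fold (adjusted p = 3.62e-10). The root-specific metal transporter Os02g0131800 was higher by 8.22 ± 0.47 (adjusted p = 3.82e-08; well above background on 1 of 3 shoot arrays). Thus 3 of 3 root markers were higher (median 10.8, and 9.30 with bounds; list adjusted p = 0.0495, and adjusted p = 0.295 with an estimated correlation). Of 43 photosynthesis genes 41 were lower in root, with a median of -7.84 (list adjusted p = 1.24e-11; adjusted p = 0.345 with an estimated correlation), and 1 was higher. Of 9 ammonium transporters 6 were higher in root and Os05g0468700 lower (-2.33 ± 0.13, adjusted p = 2.54e-08). Nitrate transporters (11 tested) and nitrogen assimilation enzymes (15) went both ways, with 4 and 5 members higher and 4 and 5 lower.

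Of 22258 genes tested between the wild-type tissues, 7479 were higher and 5612 lower in root, and 7479 and 5602 with the slide as a block. Within slides 1, 2 and 3 the median was 2.49, 2.42 and 2.61 for the higher and -2.37, -2.36 and -2.36 for the lower genes. For 2708 of the 13091 only a bound could be given. The nitrate transporter component Os02g0595900 was at least 98.1-fold higher in root, Os02g0112600 at least 10.0-fold and Os01g0704100 by 3.58 ± 0.22 (adjusted p = 6.06e-08). Os03g0291500, in the nitrogen assimilation list by its locus, was at least 428-fold higher, glutamine synthetase Os03g0223400 by 4.56 ± 0.26 (adjusted p = 3.75e-08) and glutamate dehydrogenase Os03g0794500 by 4.51 ± 0.09 (adjusted p = 3.46e-11). Lower in root were glutamate synthases Os05g0555600, at least 79.5-fold, and Os07g0658400, by -3.96 ± 0.08 (adjusted p = 2.66e-11), and the chloroplast glutamine synthetase Os04g0659100, by -4.46 ± 0.13 (adjusted p = 2.33e-10). Family member Os02g0325600 was higher in root by 3.28 ± 0.16 (adjusted p = 1.12e-08) and Os07g0119300 lower by -1.70 ± 0.19 (adjusted p = 9.09e-06), while Os03g0764600 (-0.83) and Os12g0586300 (0.52) were within 2-fold.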

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

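The effect of the knockout differed between root and shoot, by the test of the difference itself (limma, Benjamini-Hochberg adjusted p), for 128 genes, and the named genes among them are given here as the root change minus the shoot change in log2. Of the tests in this part, those of the other splits, of carry-over and of wild-type root array 1 were set down before their results were seen, and the limit on predicted signal and the set of products outside plastids were chosen only after the result was seen.

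The nitrogen genes that moved more toward a rise in root were ammonium transporters Os02g0620500 (2.61; 0.10 in shoot and 2.71 in root), Os04g0509600 (1.09) and Os05g0468700 (1.01), nitrite reductase Os01g0357100 (1.47; -0.77 and 0.70, neither past the threshold by itself) and Os08g0468700 (1.22). Glutamate dehydrogenase Os03g0794500 (-0.69), allantoin permease Os12g0503000 (-2.62; 3.24 and 0.63) and family member Os02g0325600 (-1.79) lay the other way. With the slide as a block the adjusted p was 0.111 for Os04g0509600, 0.0724 for Os05g0468700, 0.05 for Os01g0357100 and 0.0869 for Os03g0794500, whose calls were lost in 15, 14, 12 and 23 of 30 settings. Among iron and metal genes the difference was 1.76 for the helix-loop-helix gene Os03g0379300 and 5.09 for Os08g0466600, and among phosphate genes 0.95 for purple acid phosphatase Os12g0637100, -2.22 for phosphate transporter Os04g0186400 and -1.23 for SPX gene Os06g0603600, which rose in shoot and fell in root.

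Genes that rose in shoot with a smaller change in root were Os10g0419400 (-4.7), Os04g0355900 (-4.35), Os04g0249600 (-3.21), Os05g0124700 (-2.99), Os02g0221900 (-2.69), Os09g0327300 (-2), Os09g0135700 (-1.16) and Os10g0405100 (-1.1). Heat shock gene Os06g0163000 (-1.2), Rubisco gene Os12g0274700 (-4.66) and ribonuclease gene Os09g0537700 (-5.51) fell in root, with shoot changes of 0.40, -0.05 and 0.08. Genes that fell in shoot but not in root were Os10g0566400 (1.29), Os10g0508700 (1.51) and Os07g0670300 (1.52). Peroxidase Os09g0471100 (0.95), BURP gene Os11g0170900 (2.84) and cytochrome P450 Os06g0641500 (3.77) rose more in root. The differences of Os04g0355900, Os05g0124700, Os08g0466600, Os11g0170900, Os06g0641500 and Os09g0537700 are fitted values, since 1 of the groups was not well above background.

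Of 100 splits of the genotype labels within the tissues, the real one included, 2 gave as many as the 128 genes, a share under 0.05. The other one gave 304. It set wild-type shoot arrays 1 and 2 with knockout shoot array 3 against the rest and exchanged the root labels whole, so the real root split stays in it. Its count points to a structure of the samples, but the other splits drawn that kept the real root split gave 0 to 88, and the cause was not tested. With the slide as a block 100 genes were called. Exchanged genotype labels ask about any genotype effect, not about a difference between tissues. Splits that mix the genotypes also add genotype differences to the spread. A share under 0.05 was thus likely in advance and decides nothing about a difference between tissues.

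Photosynthesis transcripts lay lower in knockout root, by a median of -1.18 over 37 genes, with 0.98 on wild-type root array 1 against -0.54 and -0.90 on the other wild-type arrays, and the abundant antenna gene Os03g0592500 at 3.1, 1.92 and 1.91 on wild-type root arrays 1 to 3. Green tissue carried over into wild-type root array 1 is a candidate explanation: the excess of the 43 list members there corresponds to 0.786% of shoot RNA. The 207 shoot-specific genes left by a filter on product words showed a median of 0.579 of the excess that this share predicts (bootstrap 0.536 to 0.613). This was over the limit of 0.5 set for it. Of them, 116 had a predicted level above the lowest well-above-background signal, a choice made afterwards, and showed a median of 0.652 (bootstrap 0.614 to 0.732). The filter let some plastid products through. A set of 30 of the 116 genes, taken as outside plastids by words in their product names, showed a median of 0.697 (bootstrap 0.645 to 0.807). Product names do not show whether these genes are regulated together with plastid genes. The share therefore cannot separate carried-over tissue from regulation of shoot genes. The bootstrap drew genes on 1 array, so it does not measure the spread between arrays. Whether that array alone accounts for the shift is undecided: without it the list's median was -0.508 (list adjusted p = 2.43e-08 with the preset correlation), between the limits set for either outcome. An effect of the knockout on plastid transcripts in root stays open and was not tested separately.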

How the results depend on the processing

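The pixel mean, the scalings within tissues and leaving out both dim arrays were chosen only after the data were seen. Normexp background correction gave 30 genes in shoot, 11 in root, 2 for the difference between tissues, 5 in both tissues and 4 lists in shoot. Its median residual SD was 0.328 against 0.187, and the median absolute change of the genes called in root 0.491 against 0.857. The cause of the other shifts was not tested. With only the arrays of the groups compared, 148 genes were called in shoot, 286 in root and 25 in both, in fits with fewer samples. A minimum of 2-fold left 162, 316 and 34 by construction. Array weights gave 575, 2086, 489 for the difference and 124 in both. The authors' deposited table gave 175 in shoot and 24 in both, and the pixel mean 185 and 25. Without wild-type root arrays 1 and 3, 246 were called in root, 82 for the difference and 18 in both. With genes well above background on all 12 arrays, 8659 differed between wild-type tissues, since fewer were tested. An estimated correlation left 0 lists in shoot and 0 in root.

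Leaving out 1 array at a time gave 152 to 367 genes in shoot (154, 152 and 163 without wild-type shoot array 1, 2 or 3), 228 to 1105 in root (380, 311 and 228 without wild-type root array 1 or 3 or knockout root array 1). It gave 52 to 208 for the difference (59, 73 and 70 without wild-type shoot array 1, 2 or 3, 70 without wild-type root array 3, and 52, 70 and 208 without knockout root array 1, 2 or 3). In both tissues it gave 29 to 62 (35 and 32 without wild-type shoot array 1 or 2, 36 and 37 without wild-type root array 1 or 3, 29 and 37 without knockout root array 1 or 2). For wild-type tissues it gave 13071 to 13217, for lists 6 to 9 in shoot and 8 to 12 in root.

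The share of rises among root calls, 83.8%, was 63.1% with no filter, 49.5% in the authors' table, 45.8% from pixel means, 48.0% without both dim arrays, 64.9% without knockout root array 2 and 73.1% without wild-type root array 2. For wild-type root against shoot it was 57.1%, and 75.6% with normexp, 73.7% in the authors' table and from pixel means, and 68.8% with no filter. The median change of all genes in root was 0.01, and 0.19 with normexp, -0.12 in the authors' table and -0.13 from pixel means, so root changes under these are relative to those shifts.

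Over all settings, values of named genes were on the same side of the threshold 3818 times, lost a call 622 times, gained one 22 times and turned direction 19 times. Turned values in root were those of Os01g0870300 (-0.19 in the authors' table, -0.21 from pixel means, -0.0064 without wild-type root array 3, -0.072 without both dim arrays), Os02g0735200 (-0.25 with normexp, -0.079 without both dim arrays), Os04g0691400 (-0.13 and -0.15 in the authors' table and from pixel means), Os07g0178600 (-0.34 and -0.32) and Os11g0620300 (-0.12 and -0.11). Without wild-type root array 2, Os01g0870300 kept its direction, at 0.27. Os06g0581000 ran from -0.036 without knockout shoot array 1 to 0.20 without knockout shoot array 2. The difference between tissues of Os03g0764600 was 0.16 with quantile scaling, 0.086 without knockout shoot array 1 and 0.074 without knockout root array 3, down to -0.48 without knockout shoot array 3. Os10g0370700 between wild-type tissues, at -1.31, was 1.16 with normexp, 1.20 in the authors' table and 1.19 from pixel means. The cause was not tested.

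Calls of the family and of WRKY factors in shoot, and of the family, ammonium transporters, iron and photosynthesis in root, kept their direction and side of the threshold under all alternatives except the estimated correlation. In shoot the call of LEA proteins was lost in 15 settings, that of ammonium transporters with normexp, of fermentation with no filter, of histones with normexp, in the authors' table, from pixel means and without knockout shoot array 2, and of expansins with array weights. In root that of nitrogen assimilation was lost with normexp, and that of pathogenesis-related proteins with normexp, array weights, genes well above background on all 12 arrays, in the authors' table and from pixel means, while ribosomal proteins turned upward and histones lost the call in the authors' table and from pixel means.

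With the replicate number as a block, which is the slide as a block, 218 genes were called in shoot, 602 in root, 100 for the difference, 42 in both tissues and 13081 between wild-type tissues. The numbers do not pair the samples: 5 of 18 same-number pairs correlated above 0.1 in their deviations from the group means (from -0.258 to 0.158 over 16500 genes), and 3 of 12 arrays correlated best with their own number. Signal over background limits what the dim wild-type root arrays can show.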

Other observations

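A further 5 genes that rose in both knockout tissues are given here. They were chosen after their values were seen, as were, in this part, the tests of neighbouring loci, single probes, low signal and scaling, but not those of shared probe bases, of falls missed by the background subtraction and of the splits. Allantoinase Os04g0680400, which opens the purine ring product allantoin, rose by 1.98 ± 0.20 in shoot (limma, adjusted p = 0.000766) and 1.23 ± 0.20 in root (0.0109), amidase Os04g0184100 by 2.05 ± 0.22 (0.0013) and 1.40 ± 0.22 (0.01), and the urea transporter-like Os10g0580400 by 2.94 and 2.14. Type 1 metallothionein Os11g0704500 rose by 0.83 ± 0.15 (0.0219) and 0.69 ± 0.15 (0.0322) and ferroportin family gene Os06g0560000 by 1.01 ± 0.17 (0.0157) and 0.74 ± 0.17 (0.0382).

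Between wild-type tissues, several fixed lists lay higher in root. Of 68 class III peroxidases 57 were higher and 4 lower (median 5.59, and 4.96 with bounds; list adjusted p = 1.29e-07), of 34 expansins and xyloglucan endotransglucosylases 30 were higher (median 5.95, and 5.10 with bounds; 1.23e-06), of 41 histone and DNA replication genes 31 higher and 2 lower (median 2.89; 5.70e-06) and of 133 ribosomal proteins 90 higher (median 1.22; 5.00e-11). With an estimated correlation the last 2 lost the call (adjusted p = 0.257 for histones and adjusted p = 0.439 for ribosomal proteins). Of 12 iron genes 9 were higher and 1 lower (median 4.12, and 3.14 with bounds; 0.0196). Of 10 chlorophyll synthesis genes 9 were lower (median -7.36, and -7.03 with bounds; 0.000102) and of 7 clock genes 6 (median -2.08; 0.00483), and these 3 lost the call as well (adjusted p = 0.345 each with an estimated correlation). Peroxidases and expansins kept the call with an estimated correlation (adjusted p = 0.0291 each).

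Genes that changed the same way in both tissues were compared with their neighbours in locus order. A difference between the lines around particular loci may place them close together. Among 58 genes 2 pairs were found, Os07g0511100 with Os07g0511400, and Os05g0296800 with Os05g0297800. The 10000 random sets gave a median of 0 and a highest of 5 (permutation p = 0.12), which leaves this explanation undecided. It had first been read as excluded, and was reread because such a p excludes nothing. Fitted changes in shoot and root were 5.81 and 7.12 for Os07g0511100 and 9.94 and 9.16 for Os07g0511400. For Os05g0296800 they were 4.55 and 4.56, and for Os05g0297800 0.99 and 1.46. Both changes of Os07g0511400 exceeded the largest fitted rises of genes named by the rule, 8.55 in shoot and 6.99 in root. The count of pairs takes no account of these sizes. Probe bases shared between neighbours are argued against for these 2 pairs only, as 0% of them shared 20 bases. Whether a probe matches the transcript of the neighbouring gene was not checked, so sequence shared beyond the probes stays open. For genes with another measured probe, sequence variants under single probes are argued against as well. Of their other probe comparisons, counted per tissue, 95.2% (20 of 21) moved the same way by at least 0.5 of the change. Genes with only 1 measured probe were not covered, and for them such variants stay open. An effect of the knockout stays open.

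More genes rose than fell in knockout root (668 and 129). Low signal of wild-type root arrays 1 and 3 could favour rises: the 663 genes called as risen from slides 1 and 3 alone had on slide 2, where both arrays have like signal, a median of 0.46 against 1.01, a ratio of 0.455, between the limits set, while the 543 called as fallen lay at 0.07 against -0.999. Falls missed by the background subtraction could also contribute, and the 352 genes called as fallen only from pixel means gave a ratio of 0.362 (-0.24 against -0.66), which leaves this undecided. Scaling of the processed signal is argued against, as rises made up at least 77.6% of the calls under every other scaling of it tried. Among the root calls from pixel means or from the authors' deposited table, rises did not outnumber falls, so the excess of rises depends on the processing. An effect of the knockout on most of these genes stays open beside the first explanations.

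Of the 10 splits of the 6 arrays of a comparison, no share under 0.05 is possible. The real split gave 284 genes in shoot (1 split gave as many, the highest other 29), 797 in root (1, 6) and 13091 between wild-type tissues (1, 0). It gave 7 lists in shoot, where 2 splits gave as many, and 8 lists in root (1, 5). The highest other in shoot, wild-type arrays 1 and 3 with knockout array 2 against the rest, gave 8. The other splits gave 0 to 8 lists in shoot and 1 to 5 in root. Camera with the preset correlation thus also called lists between groups of mixed genotype. For genes changed in both tissues 1 of 100 drawn splits, the real one, gave as many as 59 (highest other 0), a share under 0.05. That share was nearly fixed in advance. A wrong split gave at most 29 genes in shoot and 6 in root, so 59 shared genes were out of reach. It therefore decides nothing about the overlap between the tissues.

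On 4 root arrays, 24 spot values had a pixel median more than 1 SD from the pixel mean of the same spot, 19 above and 5 below it. All 19 above lay on knockout root arrays and all 5 below on wild-type root array 2. Each of them thus moved the deposited medians toward a higher knockout root relative to wild-type root. Counts were 5 on wild-type root array 2 and 6, 9 and 4 on knockout root arrays 1, 2 and 3, and 0 on the other 8 arrays. Of these values 12 belonged to ammonium transporter loci Os02g0620500, Os04g0509600 and Os05g0468700, 5 to nitrate transporter loci Os01g0704100 and Os03g0235900 and 7 to other spots. The deposited table carries these medians, and their origin was not tested.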
